A study of Mus musculus with 6 samples.

How the data were processed

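RNA was measured in 6 samples of central retina from rd1/rd1 mice, 3 at 2 months and 3 at 8 months of age. Per the labels' protocols, total RNA was extracted on columns with a DNase step, its quality was checked on a Bioanalyser, and biotinylated cRNA was made for Illumina arrays, which are single-colour bead arrays. Per the series design, each sample was an independent pool of 3 to 6 punches, 1.5 mm across. Nothing says how many animals a pool held or whether pools shared an animal.

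The deposited table gives 1 value per probe and sample, 45281 probes and 6 columns, and no value is missing. The deposited values are on a log2 scale, read from their range of 6.98 to 14.5. Whether it is a plain log2 or a variance-stabilising transform that approaches log2 for bright probes cannot be read from the values, and the latter would compress the changes of dim genes. The sorted columns agree within 0.00307 at every rank, the mark of a quantile-type normalization by the authors. The software, background correction and normalization are not given in the sources used here. Detection p-values were not used here. The median of each array was 7.19. Levels near it are close to background, where differences are compressed, and signal over background rather than depth sets which genes can be measured. The arrays correlated with each other at 0.99 to 0.996 over all probes.

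Groups were taken from the sample titles, which give the age and the replicate number. The descriptions add the numbers 1, 2 and 10 for the 8 month samples and 7, 8 and 9 for the 2 month samples, with no meaning given. The descriptions number the 2 month samples 1, 1 and 2 where the titles give 1, 2 and 3, and the titles were used, so the alternative that takes the replicate number as a block rests on the titles. The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. A probe was kept when it exceeded the 50th percentile of its own array on at least 3 arrays, which left 22458 probes. Probes were named through the GEO annotation of the array, which can be old: 34885 probes had 1 gene symbol, 18 several and 10378 none. Symbols were checked through gene numbers against RefSeq gene records of assembly GRCm38.p6, which updated 0 of them, while the gene numbers of 78 named probes had no match. Each of the 12046 tested genes was represented by its kept probe with the highest mean, and 4802 genes had more than 1 kept probe. Probes of 1 gene can disagree, and the text gives such values for several of the genes it names.

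Changes are 8 months minus 2 months on the deposited log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 4 residual and 3.311 prior degrees of freedom, and the standard errors given are limma's moderated ones. No covariate and no block were used. Gene lists with at least 4 tested genes, 39 of 41, were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. The sex-linked list was given per sample and not tested, and the list of non-visual photopigments held fewer than 4 tested genes. Of 978 list entries, 4 matched no gene. With an estimated correlation 0 lists were called by camera and 4 had an unadjusted p below 0.05, so none of the 12 calls made with the preset correlation held. By fry, which tests whether the genes of a list move on balance one way, 3 lists were called: cone, cholesterol synthesis and horizontal cell (adjusted p = 0.0482, 0.0374 and 0.0374), of which 2 were among the 12 called by camera.

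The genes named are 17 anchor genes of retinal cell types, the 12 genes with the largest change in each direction among those called with no overlap between ages, and the 3 members with the smallest p of each list described. Genes with clone names kept their rank but are not named. Opn1sw, Pde6b and Calb1 did not pass the filter. Egr1, Fos, Arc, Pde6h, Mthfd2 and Chac1 were added after their values were seen.

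On simulated data with known changes for the comparison of 3 and 3 samples over 12046 genes, the test recovered 73.1% of 67 genes changed by 0.5, 97% of 67 changed by 1 and 100% of 66 changed by 2 on the log2 scale. It made 7 false calls among 187. With 187 calls the adjusted threshold is easier to pass than with the 27 calls of the real data. The simulated noise also held no variation shared between genes. The recovery is therefore probably higher than in the real data, where Opn1mw, at −2.17, did not pass (limma adjusted p = 0.143). In the same simulation camera with the preset correlation called 2 of 2 lists shifted by 0.2, out of 39 lists, and 1 list that was not shifted. The simulated genes were independent, so this says nothing about lists whose genes vary together between samples.

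The alternatives were other normalizations between arrays (quantile again, median centring, cyclic loess), no filter and a stricter one at the 70th percentile, the mean over a gene's probes, every probe on its own, limma's trend and robust prior, array weights, the replicate number as a block, only the arrays numbered 7 to 10, leaving out each sample in turn, a 2-fold minimum, camera with an estimated correlation, and fry. Chosen after seeing the data were the Eif2s3y level as a covariate, the haemoglobin level as a covariate, and leaving out 2 month replicate 2 together with 8 month replicate 3. Plots were drawn with matplotlib 3.10.9.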

Results

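Gene expression was measured on Illumina bead arrays in the central retina of rd1/rd1 mice, a strain in which a mutation of Pde6b, the beta subunit of rod phosphodiesterase, causes rods and then cones to degenerate. Samples were taken at 2 and 8 months of age, both after the loss of most rods, with 3 samples per age. Each sample was a pool of 3 to 6 punches, 1.5 mm across, from the centre of the retina. The arrays hold 45281 probes, and the deposited values are on a log2 scale that runs from 6.98 to 14.5. After a filter on dim probes, 12046 genes were tested. The number of arrays, 3 per age, limits the precision, and p-values measure the spread between these pooled samples.

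The comparison asked which genes change during late-stage degeneration, between 2 and 8 months. Arr3, the cone arrestin, fell by 1.55 on the log2 scale (SE 0.127, n = 3 per age), Tulp1, needed for protein transport to the outer segment of photoreceptors, by 1.15 (SE 0.141) and Gnat2, the cone transducin alpha subunit, by 0.86 (SE 0.0818). Egr3, Egr4 and Fosb, transcription factors that neurons switch on within minutes of activity, rose by 2.64 (SE 0.138, 6.25-fold), 2.26 (SE 0.215) and 0.92 (SE 0.0857). Vgf, a neuropeptide precursor, rose by 1.09 (SE 0.0589), Tac1, the precursor of substance P, by 1.00 (SE 0.130) and Vip, which codes for vasoactive intestinal peptide, by 0.83 (SE 0.0675). Over all tested genes the median change was 0.000482 and the median standard error 0.0654.

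In all, 19 genes were higher and 8 lower at 8 months at an adjusted p below 0.05 (limma, Benjamini-Hochberg over 12046 genes), and in all 27 the 3 values of 1 age lay above the 3 values of the other. Of these, 4 were at least 2-fold higher and 2 at least 2-fold lower. The 27 are few beside the 1257 genes with an unadjusted p below 0.05, of which 614 were higher and 643 lower, against 602 expected by chance. Genes vary together, so that chance count is not firm: divisions of the 6 samples that mix the ages gave 374 to 1041 such genes. The ages did not overlap for 1812 genes, or 15% of those tested, where chance gives 10%.

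The cone list, fixed before the arrays were read, held 14 tested genes. Over all genes 2 of them fell, Arr3 from 9.24 ± 0.0943 to 7.68 ± 0.263 (SD, n = 3) and Gnat2 from 9.51 ± 0.121 to 8.65 ± 0.110. Adjusted over the list alone, 9 members were lower and none higher. The medium-wavelength opsin Opn1mw had the change of −2.17 (SE 0.442), with an adjusted p of 0.143 (limma), and the cone phosphodiesterase Pde6c that of −2.09 (SE 0.349), with an adjusted p of 0.0987. For both, 8 month replicate 3 was the lowest sample, with Opn1mw at 8.92 against 10.6 and 10.7 in the other samples of that age. The list had a median change of −0.58 and fell by camera with a preset correlation (adjusted p = 6.97e-08), but not with an estimated correlation (adjusted p = 0.408). Its median was −0.12 with no filter on dim probes and −0.83 with a stricter one. Both probes of the short-wavelength opsin Opn1sw stayed below the filter, at 7.08 to 7.15 on average at both ages.

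All 19 tested genes of the general photoreceptor list, which rods and cones share, had negative changes. Over all genes 1 of them fell, Tulp1, from 9.29 ± 0.198 to 8.14 ± 0.246. Adjusted over the list alone, 9 were lower. Aipl1, a chaperone of phosphodiesterase, had a change of −1.12 (SE 0.194, and −0.52 at the probe that moved least), and Prom1, a membrane protein of the outer segment discs, one of −0.34 (SE 0.0626). The list fell by camera with a median of −0.20 (adjusted p = 2.99e-11 with the preset and adjusted p = 0.411 with an estimated correlation). The kept probes of Tulp1 differed, with changes from −1.15 to −0.20, and another probe of Prom1 had a change of 0.06.

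Rod genes were mixed, but several were too dim to fall far. Pde6a, Guca1b, Samd7 and Cnga1 lay at 7.20 to 7.31 at 2 months, close to the array median of 7.19, so the list median says little. The list of 14 tested genes had a median change of −0.03 and did not pass camera (adjusted p = 0.082). It passed without 2 month replicate 3 or 8 month replicate 1 (adjusted p = 0.0319 and 0.037). Its median was 0.005 without 2 month replicate 1 and −0.04 without 8 month replicate 1. No member passed over all genes, and adjusted over the list alone 4 were lower. Pde6g, the inhibitory subunit of rod phosphodiesterase, had a change of −1.35 (SE 0.183, adjusted p = 0.0522 by limma), Sag, the rod arrestin, one of −1.81 (SE 0.315, and −0.23 at its other probe), and Rdh12, a retinol dehydrogenase of photoreceptors, one of −0.34 (SE 0.0919, and −0.02 at its other probe). Gnat1, the rod transducin alpha subunit, was at 7.57 ± 0.0743 at 2 months and 7.73 ± 0.246 at 8 months. The probe of Pde6b, the gene mutated in rd1, was close to the median of its arrays at both ages, at 7.15 and 7.18.

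**Figure D1:**
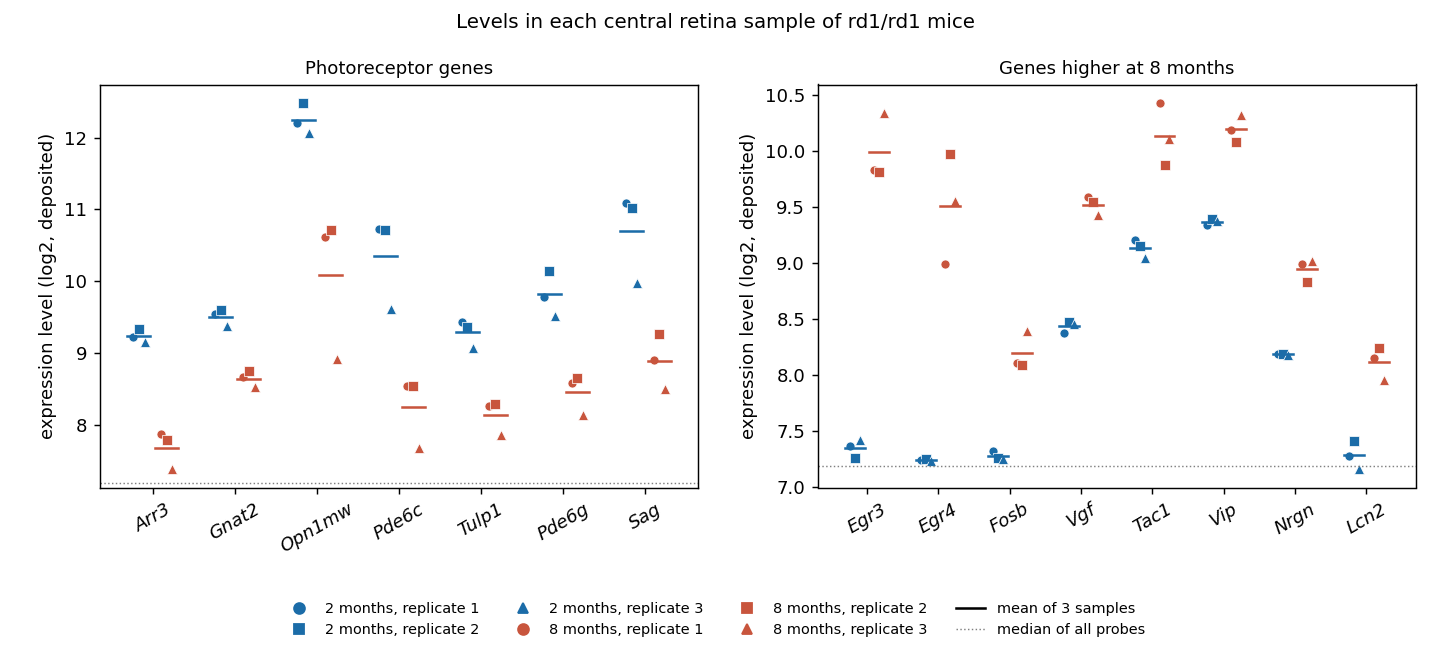
Expression level on the deposited log2 scale (vertical axis) of 7 photoreceptor genes and of 8 genes higher at 8 months, in each of the 6 samples; circle, square and triangle mark replicates 1, 2 and 3, blue 2 months and red 8 months, lines are means of 3 samples and the dotted line is the median of all probes. Arr3 lies at 9.15 to 9.34 in the 2 month samples and at 7.38 to 7.88 in the 8 month samples, and Egr3 at 7.26 to 7.42 and at 9.81 to 10.3.

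Among the 21 tested immediate early genes, 3 rose over all genes. Egr3 went from 7.35 ± 0.0809 to 9.99 ± 0.297 and Egr4 from 7.24 ± 0.0117 to 9.51 ± 0.494, both zinc finger transcription factors, while Fosb, a partner in the AP-1 complex, went from 7.27 ± 0.0396 to 8.20 ± 0.17. Adjusted over the list alone, 8 members were higher and 1 lower. Arc, Egr1 and Fos, chosen after their values were seen, had changes of 0.89 (SE 0.171), 1.99 (SE 0.386) and 1.16 (SE 0.353). The median of the list was 0.05 and its mean 0.52, with 15 members positive and 6 negative, and leaving out 1 sample gave medians from 0.05 to 0.27. The list rose by camera (adjusted p = 1.74e-05 with the preset and adjusted p = 0.411 with an estimated correlation). At 2 months Egr3, Egr4 and Fosb lay close to the array median of 7.19, where values are compressed, so their folds are probably understated, and the second probe of Egr3 changed by only 0.03.

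Of 22 tested genes of amacrine cells, the inhibitory interneurons of the inner retina, 2 rose over all genes, Vip and Tac1. Adjusted over the list alone, 4 were higher and 2 lower. Gad2, an enzyme that makes the transmitter GABA, had a change of 0.51 (SE 0.0964, adjusted p = 0.135 by limma). The list had a median change of 0.13 and rose by camera (adjusted p = 0.000479 with the preset and adjusted p = 0.408 with an estimated correlation), and its median was 0.08 without 8 month replicate 3.

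Other genes rose as well. Nrgn, a calmodulin-binding protein of neurons, rose by 0.76 (SE 0.0607), Gng4, a G protein gamma subunit, by 0.76 (SE 0.101), and Vgf went from 8.43 ± 0.0509 to 9.52 ± 0.0809. Lcn2, a lipocalin released by reactive glia, rose by 0.83 (SE 0.0929), Prss56, a serine protease made by Müller glia, by 0.78 (SE 0.0954), and Gamt, an enzyme of creatine synthesis, by 0.73 (SE 0.0898). The largest of their adjusted p-values was 0.0498 (limma). Of the 12 largest rises, 1 belongs to a gene with a clone name and is not named. Beyond the photoreceptor genes, 5 genes fell: P2ry14, a receptor for nucleotide sugars, by 0.50 (SE 0.0564), Pcsk6, a proprotein convertase, by 0.42 (SE 0.0535), Wnk4, a kinase, by 0.40 (SE 0.0486), Macrod1, an ADP-ribose hydrolase, by 0.40 (SE 0.0525), and Slc7a3, a cationic amino acid transporter, by 0.36 (SE 0.0454). The other probe of Slc7a3 had a change of 0.05, and the smallest change among the probes of Wnk4 was −0.14.

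The lists for 4 other retinal cell types did not pass camera with all 6 samples. Bipolar cell genes (20 tested) had a median change of −0.06 (adjusted p = 0.0771, and 0.0369 and 0.0338 without 2 month replicate 1 or 2), with Prkca at −0.21 (SE 0.0782, and −0.01 at its other probe) and the receptor Grm6 at −0.07 (SE 0.0556). Horizontal cell genes (10 tested) had a median of −0.10 (adjusted p = 0.108), with the transcription factor Lhx1 at −0.44 (SE 0.0611, adjusted p = 0.0555 by limma, and −0.20 at its other probe). Adjusted over the list alone, 1 horizontal cell gene was higher and 2 lower. Ganglion cell genes (19 tested) had a median of 0.04 (adjusted p = 0.18), which was 0.12 without 8 month replicate 2 (adjusted p = 0.000141), and Opn4, the photopigment melanopsin, was close to the array median at both ages, at 7.26 and 7.22. Müller glia genes (22 tested) had a median of −0.08 (adjusted p = 0.276), with Rlbp1 at −0.18 (SE 0.112) and Glul at −0.20 (SE 0.0842). No gene of these 4 lists passed over all genes, and no bipolar, ganglion cell or Müller glia gene passed when adjusted over the list alone. Calb1, expressed in horizontal cells, stayed below the filter, at 7.12 and 7.14.

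In the reactive gliosis list (20 tested, median 0.06, camera adjusted p = 0.108) Lcn2 rose, while Gfap, the filament of reactive glia, was at 10.6 ± 0.686 at 2 months and 10.8 ± 0.139 at 8 months (limma adjusted p = 0.921). Adjusted over the list alone, 1 was higher and 1 lower, the latter Ednrb, an endothelin receptor, at −0.61 (SE 0.116, and −0.18 at its other probe). Microglia and macrophage genes (26 tested) had a median of −0.01 (adjusted p = 0.234), with Aif1 at −0.04 (SE 0.0658) and C1qa at 0.15 (SE 0.113), and interferon response genes (25 tested) a median of 0.08 (adjusted p = 0.0755). Over all genes and adjusted over the list alone, none of the last 2 lists passed. Gliosis, microglia and interferon levels were lowest in 2 month replicate 3, at −0.33, −0.16 and −0.26 relative to the mean of all samples. Without 2 month replicate 2 the interferon response list rose by camera (median 0.19, adjusted p = 4.94e-08), as did reactive gliosis (median 0.11, adjusted p = 0.0221). Without 2 month replicate 3 their medians were 0.03 (adjusted p = 0.968) and −0.08 (adjusted p = 0.231), and the microglia list fell (median −0.10, adjusted p = 3.05e-05). Gliosis also passed without 2 month replicate 1 (adjusted p = 0.0041) and interferon without 8 month replicate 2 (adjusted p = 0.0115). These calls used the preset correlation, while those estimated with all samples were 0.61 for interferon, 0.309 for gliosis and 0.609 for microglia. Divisions of the 6 samples that mix the ages gave camera p-values down to 7.58e-17, 5.54e-05 and 1.37e-10, so such calls alone do not point to age. Genes of MHC class I and peptide loading rose by camera (19 tested, 18 of them positive, median 0.09, adjusted p = 0.00127 with the preset and adjusted p = 0.411 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. The call was lost without 2 month replicate 3 (median 0.07, adjusted p = 0.0731). Their leading members were Psmb10, an immunoproteasome subunit, at 0.36 (SE 0.0859), H2-Q8 at 0.15 (SE 0.0471) and H2-K1 at 0.31 (SE 0.0978). The other probes of these genes had changes of 0.21, 0.003 and 0.08.

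Of 17 tested genes of cholesterol synthesis, 15 had positive changes, with Msmo1 at 0.26 (SE 0.0632), Stard4 at 0.41 (SE 0.107) and Fdps at 0.18 (SE 0.0590, and −0.001 at its other probe). None passed over all genes and 2 were higher when adjusted over the list alone. The list rose by camera with a median of 0.16 (adjusted p = 1.64e-05 with the preset and adjusted p = 0.284 with an estimated correlation). Genes of cytosolic ribosomal proteins fell slightly, with 29 of 38 negative and a median of −0.06 (camera adjusted p = 0.00514 with the preset and adjusted p = 0.411 with an estimated correlation). Rpl22 had a change of −0.22 (SE 0.0596), Rps9 of −0.14 (SE 0.0444) and Rps4x of −0.15 (SE 0.0580). None of them passed over all genes or adjusted over the list alone, and the call of the list was lost without 2 month replicate 1 (median −0.02, adjusted p = 0.273).

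**Figure D2:**
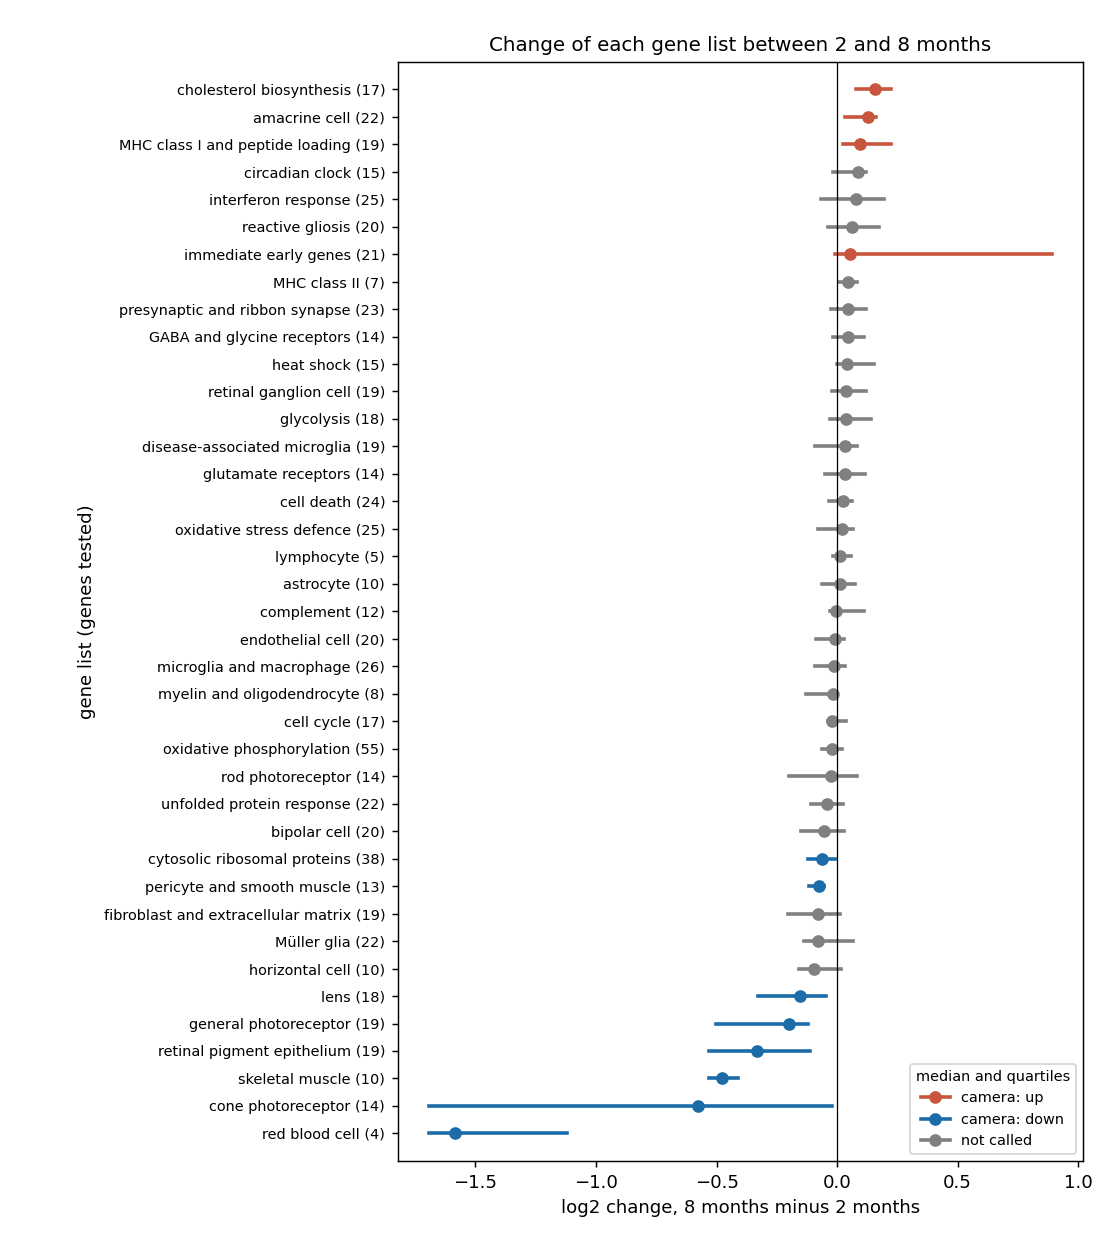
Median log2 change between 8 and 2 months (horizontal axis, points) with quartiles of the members (lines) for the 39 tested gene lists; colour marks the 12 lists called by camera with the preset correlation, 4 up and 8 down. The red blood cell list lies lowest, at −1.59, and the cholesterol synthesis list highest, at 0.16.

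Genes of tissues next to the neural retina were measured as well. Haemoglobin genes were higher in every 2 month sample, with Hbb-bs at 11.5 ± 0.798 at 2 months and 9.78 ± 0.0530 at 8 months. Its probes had changes from −1.69 to −0.69. The red blood cell list (4 tested) had a median of −1.59 and fell by camera (adjusted p = 0.000214 with the preset and adjusted p = 0.411 with an estimated correlation), with 3 lower when adjusted over the list alone. Pigment epithelium genes (19 tested, 18 negative) fell by camera with a median of −0.33 (adjusted p = 0.000154 with the preset and adjusted p = 0.435 with an estimated correlation), with Dct at −1.30 (SE 0.503), Tyrp1 at −0.98 (SE 0.387, and −0.15 at the probe that moved least) and Rpe65 at −0.33 (SE 0.279). Skeletal muscle genes (10 tested, all negative) fell with a median of −0.48 (camera adjusted p = 0.000426 with the preset and adjusted p = 0.435 with an estimated correlation). Lens genes (18 tested) fell with a median of −0.15 (camera adjusted p = 0.0172 with the preset and adjusted p = 0.645 with an estimated correlation), and pericyte and smooth muscle genes (13 tested) with a median of −0.07 (camera adjusted p = 0.00645 with the preset and adjusted p = 0.451 with an estimated correlation). No gene of these 5 lists passed over all genes, and apart from the 3 haemoglobin genes 1 was lower when adjusted over the list alone, the pericyte gene Vtn, at −0.81 (SE 0.130). Leaving out 1 sample gave medians from −0.46 to −0.10 for pigment epithelium, −0.74 to −0.20 for muscle and −1.83 to −1.14 for red blood cells, each list staying called, and ended the call of the lens list without 2 month replicate 3, 8 month replicate 2 or 8 month replicate 3 (medians −0.04, −0.06 and −0.11, adjusted p = 0.227, 0.183 and 0.176) and that of the pericyte list without 2 month replicate 2 or 3 (medians −0.07 and −0.10, adjusted p = 0.056 and 0.0713).

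These signals were uneven within an age. In 2 month replicate 2 the muscle gene Myl1 reached 11.1, against 9.32 and 7.31 in the other 2 month samples, and the pigment gene Dct 12.3, against 10.4 and 10.9. Myl1 lay at 7.14 to 7.52 in the 8 month samples, a range that holds 2 month replicate 3. The pigment epithelium list was lowest in 8 month replicate 3, at −0.52 relative to the mean of all samples, the sample that was also lowest for cone genes, at −0.74. The Y-linked gene Eif2s3y, whose probes did not pass the filter, was, at its brighter probe, at 7.79 and 8.27 in 2 month replicates 1 and 2 and between 7.10 and 7.18 in the other 4 samples. Xist, transcribed from the inactive X chromosome, was at 9.40 and 8.73 in those 2 samples and between 10.5 and 11.1 in the others.

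**Figure D3:**
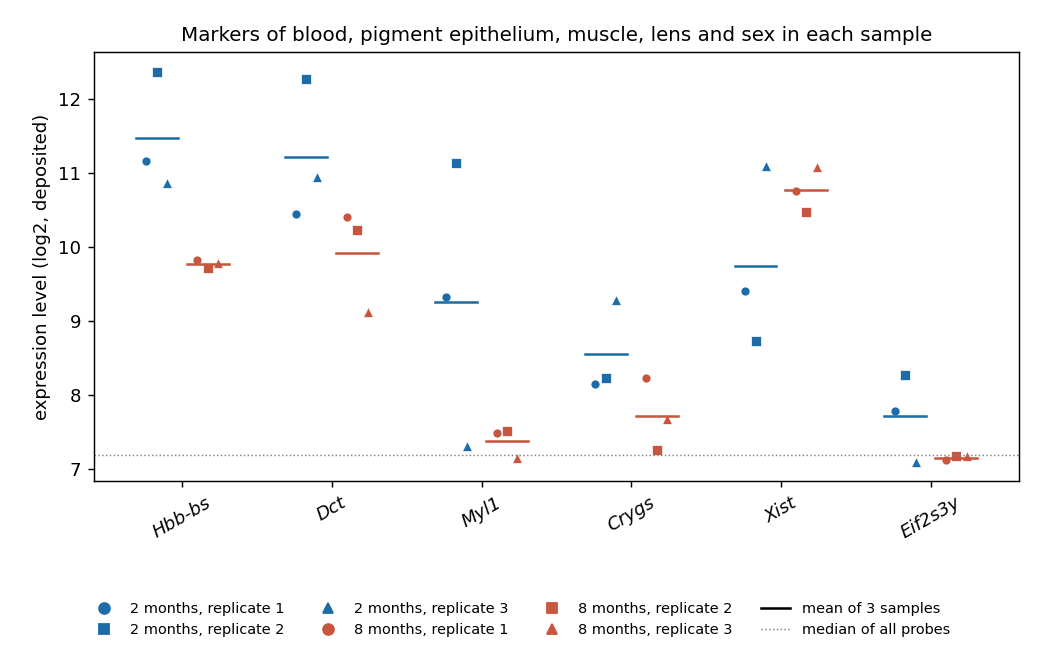
Expression level on the deposited log2 scale (vertical axis) of marker genes of blood (Hbb-bs), pigment epithelium (Dct), muscle (Myl1), lens (Crygs) and sex (Xist, Eif2s3y) in each sample; circle, square and triangle mark replicates 1, 2 and 3, and lines are means of 3 samples. Hbb-bs lies at 10.9 to 12.4 in the 2 month samples and at 9.72 to 9.83 in the 8 month samples.

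The number of called genes depended on single samples: leaving out any 1 of the 6 left 2 to 12 genes higher and 0 to 19 lower (limma), with 0 lower without 2 month replicate 1, where 593 were lower at an unadjusted p below 0.05. With the haemoglobin level as a covariate, chosen after seeing the data, limma called 0 genes higher and 0 lower, with 461 and 378 at an unadjusted p below 0.05. The 19 named called genes had a median share of 0.982 of their change (0.761 to 1.29), and their median standard error went from 0.0857 to 0.171. Called genes have little spread within an age beside their change, so a high share kept decides nothing about blood content.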

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

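The tests with the Eif2s3y level or the haemoglobin level as a covariate, and with 2 month replicate 2 and 8 month replicate 3 both left out, were chosen only after the results were seen. The other log offsets were not run, because the values already were on a log scale. All 19 of the called genes named by the rule kept their direction under every alternative that gave them a value. Adjusted p-values over those alternatives ran from 7.34e-08 to 0.187 for Egr3 and from 2.1e-06 to 0.371 for Arr3. Quantile normalization again, median centring, cyclic loess and array weights called 18 to 20 genes higher, 8 to 10 lower and 11 or 12 lists, against 19, 8 and 12. The mean over probes called 13 genes higher, 6 lower and 13 lists.

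Fewer or more genes tested moved the counts: 5 higher and 2 lower with no filter, 38 and 36 with the stricter filter, and 8 and 3 with every probe tested. The trend and robust prior called 52 higher and 52 lower, of which 18 and 8 were among the original calls; the cause was not tested. A 2-fold minimum left 4 higher and 2 lower. Only arrays numbered 7 to 10, with 1 sample at 8 months that is assumed to vary like the others, called 2 higher, 2 lower and 20 lists. Leaving out 1 sample gave 2 to 12 genes higher and 0 to 19 lower, and lists from 11 to 16. The lowest gene counts came without 2 month replicate 1, and without 2 month replicate 3 the 19 lower genes included 3 of the original 8. With an estimated correlation 0 lists were called, 4 at an unadjusted p below 0.05, and by fry 3, of which 2 were among the 12.

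Over all alternatives the medians of the 12 called lists ran from −0.835 to −0.116 for cone (past the threshold under 20 of 21), −0.356 to −0.119 for general photoreceptor (19), 0.0769 to 0.206 for cholesterol (19), 0.0363 to 0.37 for immediate early (19), 0.0763 to 0.165 for amacrine (19), 0.0659 to 0.235 for MHC class I (18), −0.735 to 0.689 for skeletal muscle (18), −0.679 to 0.0219 for pigment epithelium (17), −1.83 to −0.0115 for red blood cell (17 of 20), −0.0936 to −0.0177 for ribosomal (17), −0.179 to −0.0428 for pericyte (15) and −0.34 to −0.0431 for lens (14). Of the 27 lists not called, interferon response passed under 7 of 21 (adjusted p down to 6.31e-16), the unfolded protein response under 6 (0.004), reactive gliosis (5e-06) and rod (0.00293) under 5, MHC class II (0.000543, of 20), bipolar (0.0113) and heat shock (0.00464) under 4, microglia (3.05e-05), fibroblast (0.00624) and oxidative stress (0.0106) under 3, and ganglion cell (0.000141), disease-associated microglia (0.00304), complement (0.00443) and endothelial (0.00464) under 2. Horizontal cell (0.0374), Müller glia (0.00137), astrocyte (0.0059), lymphocyte (0.0415, of 20), oxidative phosphorylation (0.0054), presynaptic (0.033) and glutamate receptor (0.0301) lists passed under 1, and the other 6 under none. These counts take calls in either direction. That of skeletal muscle includes a rise by camera under the haemoglobin covariate (adjusted p = 2.77e-05). So do those of microglia (0.0172), fibroblast (0.0102), endothelial (0.0482) and astrocyte (0.0059), whose direction was down with all samples and no covariate. That of microglia also includes a rise under the Eif2s3y covariate (0.00781). The causes were not tested.

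Whether replicate numbers pair the samples stays open. The deviations of samples with equal numbers correlated weakly, at 0.0239, 0.139 and 0.16, yet each 2 month sample correlated best with its own number, a hint from the data only. With the replicate number as a block, 14 genes were higher, 18 lower and 12 lists called, with 12 and 3 of the original genes among them.

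With the Eif2s3y level as a covariate limma called 2 genes higher, 0 lower (504 at an unadjusted p below 0.05) and 19 lists. With the haemoglobin level it called 0 and 0 (461 and 378 unadjusted) and 19 lists. The 19 named called genes had a median share of 0.975 of their change with the former (0.861 to 1.14) and 0.982 with the latter (0.761 to 1.29). Their median standard error went from 0.0857 to 0.104 and 0.171, so the calls ended mainly with wider errors. A called gene has a spread within an age that is small beside its change, which leaves a covariate little to take up. The shares therefore do not decide whether blood content or sex plays a part. Each covariate takes a degree of freedom and is correlated with age. With 2 month replicate 2 and 8 month replicate 3 left out, 4 genes were higher and 4 lower.

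Some directions, given as median or gene log2 changes, turned. Under the haemoglobin covariate these were lists called without it, red blood cell (−0.0115, which the adjustment for 3 of its own 4 genes sets near 0), retinal pigment epithelium (0.0219) and skeletal muscle (0.689), and lists not called without it, astrocyte (0.12), microglia (0.0929), endothelial (0.0922), fibroblast (0.211) and myelin (0.0634). So did Prkca (0.0434), Aif1 (0.0914), Rpe65 (0.118), Sncg (−0.0273), Gpr143 (0.0219), Dct (0.480), Tyrp1 (0.629), Tnnt1 (0.0817), Myl1 (1.67) and Hbb-bt (0.0890, a gene of the covariate itself). Under the Eif2s3y covariate, skeletal muscle (0.0383), astrocyte (0.0542), microglia (0.0768) and Aif1 (0.0554) turned. With both samples left out, the ganglion cell (0.0134), Müller glia (−0.0193), astrocyte (0.0223), lymphocyte (0.00283), endothelial (0.0374), fibroblast (0.0235), oxidative phosphorylation (−0.0104), cell cycle (−0.0233) and myelin (0.0277) lists turned by camera, as did Aif1 (0.00583) and Rpe65 (0.14). On arrays 7 to 10 astrocyte (−0.00229), complement (0.0432), oxidative stress (−0.0567), Gnat1 (−0.0169) and Opn4 (0.0234) turned. With no filter or the stricter one the cell cycle list (0.00156) turned, with the stricter one complement (−0.00828), and with array weights endothelial (−0.00401). Where a list's median kept its sign, only the camera direction turned.

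Leaving out 1 sample turned the direction of lists that were not called, whose medians then ran from −0.082 to 0.128 for reactive gliosis, −0.0821 to 0.0208 for astrocyte, −0.0963 to 0.0248 for microglia, 0.00285 to 0.0295 for disease-associated microglia, −0.0857 to 0.0848 for complement, 0.025 to 0.186 for interferon, −0.0382 to 0.0673 for lymphocyte, −0.104 to 0.0254 for endothelial, −0.037 to 0.00169 for oxidative phosphorylation, −0.00697 to 0.0425 for oxidative stress and −0.0281 to 0.0143 for cell cycle. Medians of the pigment epithelium list, which stayed called, ran from −0.462 to −0.104, with Dct from −1.69 to −0.771 and Tyrp1 from −1.28 to −0.513. The genes whose direction turned were Gfap (−0.228 to 0.3996), Opn4 (−0.0631 to 0.00338) and Rpe65 (−0.516 to 0.00911). The causes were not tested. Dim genes are limited by signal over background, since near the array median of 7.19 a change is compressed.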

Other observations

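Among the tests below, those of dissection stress, time of day, mixed sexes, dilution by other tissue and single samples were chosen only after the result was seen, and the stress test and the rule for single samples were also changed after a first version had been run. Other gene groups moved little. Genes of the presynaptic and ribbon synapse (23 tested, median 0.05, camera adjusted p = 0.108), of GABA and glycine receptors (14, median 0.05, adjusted p = 0.164), of glutamate receptors (14, median 0.03, adjusted p = 0.327), of glycolysis (18, median 0.04, adjusted p = 0.164) and of oxidative phosphorylation (55, median −0.02, adjusted p = 0.302) did not pass. Nor did genes of heat shock (15, median 0.04, adjusted p = 0.0771), the unfolded protein response (22, median −0.04, adjusted p = 0.108), oxidative stress defence (25, median 0.02, adjusted p = 0.588), cell death (24, median 0.02, adjusted p = 0.483), the cell cycle (17, median −0.02, adjusted p = 0.739) and the circadian clock (15, median 0.08, adjusted p = 0.275). No gene of these 11 lists passed over all genes, and adjusted over the list alone 1 heat shock gene was higher and 1 gene each of the unfolded protein response and the clock lower.

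Further cell types did not pass either by camera's adjusted p: disease-associated microglia (19 genes, median 0.03, adjusted p = 0.582), complement (12, median −0.00283, adjusted p = 0.856), MHC class II (7, median 0.05, adjusted p = 0.279), lymphocytes (5, median 0.01, adjusted p = 0.739), astrocytes (10, median 0.01, adjusted p = 0.725), endothelium (20, median −0.00693, adjusted p = 0.631), fibroblasts and matrix (19, median −0.08, adjusted p = 0.137) and myelin (8, median −0.02, adjusted p = 0.469). No gene of these 8 lists passed over all genes, and adjusted over the list alone 2 genes of disease-associated microglia were higher and 1 lower. The median, mean and camera direction differed in sign for disease-associated microglia, oxidative stress defence, astrocytes and complement.

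The 6 samples can be parted into 3 and 3 in 10 ways. The split by age called 27 genes, reached by 1 split, and the highest of the others called 1. At an unadjusted p below 0.05 (limma) it gave 1257 genes, and the highest of the others gave 1041. For lists the split by age called 12, reached by 3 splits, and the highest of the others also called 12. These 10 splits are too few for a share under 0.05. Of the 12 called lists, 6 had their smallest p in the split by age (cone, general photoreceptor, amacrine, red blood cell, cholesterol synthesis and ribosomal proteins), and 6 had another split with a p as small. The first component of the samples held 42.7% of the variance and set 2 month replicate 2 apart, at −15.9 against −5.03 to 10.6 in the others. It also parted the ages, with the 2 month samples at −15.9 to −0.886 and the 8 month samples at 4.49 to 10.6.

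Egr3, Egr4 and Fosb rose, and adjusted over the list alone 8 of 21 immediate early genes were higher. Cell stress during dissection stays open: the 36 tested immediate early and heat shock genes had a median change of 0.0483 (exact interval 0.0159 to 0.18), under the bound of 0.5 set as a sign against, but that bound was set with both medians known, members went both ways, and 11 of 15 heat shock genes were positive, 1 of them higher over the list alone. Mixed sexes in the 2 month samples stay open. With the Eif2s3y level as a covariate the 8 raised members kept a median share of 0.993 of their change (0.89 to 1.08). But they were picked from these data at an unadjusted p below 0.05, and Eif2s3y varied mainly within the 2 month samples. The test so rests on 2 month replicate 3, the only sample of its age with a low Eif2s3y level. There Egr3 was at 7.42, against 7.26 and 7.37 in the other 2 month samples and 9.81 to 10.3 at 8 months. Sampling at another time of day stays open: 9 clock output genes had a median absolute change of 0.121 (0.07 to 0.229), under the bound of 0.3 set for it, but that bound assumed an amplitude, and Dbp was at −0.39 and Nr1d1 at −0.23. A rise in neuronal activity with age may also account for it and cannot be told apart from it. A list of later-response genes was written without Vgf, Nrgn and Tac1, whose rises had been seen. Its 17 tested genes had a median of 0.0215 (exact interval −0.0446 to 0.122) and did not pass camera (p = 0.313), which had been set as a sign against. Yet Gadd45b at 0.29 and Dusp4 at −0.30 went opposite ways, so the median does not decide.

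The cone and general photoreceptor lists fell by camera with the preset but not with an estimated correlation (adjusted p = 0.408 and 0.411). Dilution of the retina by other tissue would lower all retinal genes, yet the 64 tested genes of bipolar cells, Müller glia and amacrine cells had a pooled median of 0.0107 (−0.077 to 0.0483). The pool joins lists that moved in opposite directions: the medians were 0.13 for amacrine, −0.06 for bipolar and −0.08 for Müller glia, against −0.58 for cone. Blood, pigment epithelium, muscle and lens lists also had negative medians, from −1.59 to −0.15. The single low sample, 8 month replicate 3, is not the whole source: without it the cone list had a median of −0.458 (adjusted p = 4.97e-09, over all alternatives 9.99e-12 to 0.408), and the 11 of its 14 members with negative changes kept a median share of 0.826 (0.747 to 0.954). That interval, like the one of the pooled lists, runs over genes on the same arrays (estimated correlation 0.21 for cone), so it does not measure the spread between samples. Relative to the mean of all samples, the cone list was at −0.283 and −0.264 in the other 8 month samples and at 0.257 to 0.533 at 2 months. Continued loss of cones with age, or lower expression in those that remain, may explain the pattern as a hypothesis. The arrays do not separate the 2. Pde6h, a cone phosphodiesterase subunit chosen after its value was seen, went from 11.9 ± 0.434 to 9.40 ± 0.976 (SD, n = 3 per age). That is a change of −2.47 (SE 0.458, limma adjusted p = 0.123), which left its 8 month mean above background.

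The blood, pigment epithelium and muscle lists fell by camera with the preset but not with an estimated correlation (adjusted p = 0.411, 0.435 and 0.435), no member passed over all genes, and 2 month replicate 2 was highest in all 3. Carry-over into that sample is not the whole source for blood: Hbb-bs was at 11.2 and 10.9 in the other 2 month samples, against 9.72 to 9.83 at 8 months. The 4 genes of the blood list varied together (estimated correlation 0.945), so its p and share interval do not measure the spread between samples. The same limit holds for the pigment epithelium and muscle lists (estimated correlations 0.338 and 0.488). Without 2 month replicate 2 that list had a median of −1.14 (camera adjusted p = 9.49e-09 with the preset correlation), and its 4 genes kept a median share of 0.718 (0.621 to 0.733). For pigment epithelium the median was −0.184 (adjusted p = 0.00311) and the share 0.651 (0.522 to 0.839) over the 18 negative members; with 8 month replicate 3 left out too the median was −0.0408 (adjusted p = 0.201), but these are the highest and lowest samples of their ages for this list, so their removal had to shrink it and decides nothing. For muscle, a median of −0.195 (adjusted p = 0.0095) and a share of 0.406 (0.234 to 1.02) leave carry-over open. Relative to the mean of all samples, the muscle list was at 0.201, 0.955 and −0.301 in 2 month replicates 1, 2 and 3. The 8 month samples ran from −0.365 to −0.182, so the difference was not shared by all 2 month samples. A difference in blood content or vessels with age stays open for the haemoglobin genes and had no test of its own. Of the vessel lists, endothelium had a median of −0.00693 (camera adjusted p = 0.631) and pericytes and smooth muscle one of −0.07 (camera adjusted p = 0.00645), both with the preset correlation.

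Slc7a3, an amino acid transporter, and Mthfd2, an enzyme of mitochondrial one-carbon metabolism at −0.54 (SE 0.0779) that did not pass, prompted the hypothesis that the transcriptional response to amino acid shortage was lower at 8 months. A list of 23 other genes of that response, written before its test, had a median of −0.11 (−0.157 to −0.029), with 19 negative, and shifted down by camera (p = 0.00016), but not with an estimated correlation (p = 0.134). Of these, 5 also belong to the unfolded protein response list, already seen, among them Chac1 at −0.67 (SE 0.114), and the other 18 had a median of −0.0883 (p = 0.00352, or 0.148 with an estimated correlation). Another split of the samples gave the list a smaller p, 7.77e-05. Nupr1, a member of the list, went the other way at 0.66 (SE 0.143), so the hypothesis may hold for part of the response at most.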
